A study of Mus musculus with 4 samples.

How the data were processed

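CD4+ T cells were sorted from the inguinal lymph nodes of DBA/1 mice, and 1 10x Genomics 3' library was made per group from a pool of 4 mice: young control, young GIA, old control and old GIA. The deposited matrices hold counts: whole numbers of UMIs per gene and cell barcode, for 32285 genes of the mm10 annotation. The labels give Cell Ranger 6.0.1 for every library, whereas per the file headers the control matrices were written by version 7.0.1 and the GIA matrices by 6.0.1; whether introns were counted is not stated. The labels give 10000 cells per group or mouse, in wording that leaves open which, against 8655, 7865, 9050 and 11045 barcodes (young control, young GIA, old control, old GIA). Median UMIs per barcode were 5127, 5505, 4566 and 4957. At this depth a gene with 0 UMIs among CD4 T-like cells lies under a floor of 3 counts. Cell types were rebuilt from clusters, and no annotation by the authors was used here.

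Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept (7812, 7573, 8714 and 10808). Scrublet, run through scanpy 1.11.5 per library, called 1, 2, 1 and 0 cells as doublets, where 6.92%, 6.29%, 7.24% and 8.84% are expected from the barcode numbers, so the caller did not work and doublets remain among the 7811, 7571, 8713 and 10808 cells that shares are counted over; an alternative removed the 622, 548, 761 and 1006 cells with the highest scores. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were taken without T cell receptor segments, immunoglobulin, mitochondrial, ribosomal and sex-linked genes. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), with no batch correction since library and group coincide. Clusters were named "-like" from fixed marker lists. The scoring was set after the data were seen: within each library a marker counted as up when at least 1.25-fold over the other clusters with at least 5 CPM, with a pseudocount of 5 CPM, a name needed at least 3 markers up and a positive mean score, and names of cells other than T cells also needed low T cell receptor genes. The first form of the scoring, at 1.5-fold, named the largest GIA Tfh-like cluster lymphoid tissue inducer-like and left some control naive-like clusters unnamed.

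UMIs were summed per library over CD4 T-like cells, or within a class of at least 100 cells, and scaled to the total of the same cells. Each level carries an exact Poisson 95% interval, each share an exact binomial interval, each ratio of levels or of shares an exact conditional binomial interval (for ratios of large shares wider than needed, since it treats cell numbers as Poisson counts), and each ratio of ratios an interval from simulated counts. A list member was measured with at least 30 UMIs over the 4 libraries (14951 genes passed) and was called higher or lower at 1.5-fold with an interval that excludes 1. List medians were set against 10000 random lists matched on expression in 20 bins. Named genes followed a rule: at least 20 CPM in the higher library and at least 100 UMIs in the pair of libraries, then the 12 highest and 12 lowest by the interval bound nearest to 1, with 5 and 5 within each class and 8 and 8 for the age difference in the GIA effect. Immunoglobulin genes, T cell receptor segments, mitochondrially encoded and sex-linked genes were left out. Examples from lists are the members with the largest ratios, and 7 genes (Foxp3, Cxcr5, Pdcd1, Cd44, Il17a, Ifng and Tnfsf8) are given in every comparison. A further gene fixed in advance, the planned gate for naive cells that uses it, and 1 gene named by the rule in a class are not reported here. Grouping, filters, marker and gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined.

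Alternatives fixed in advance were a looser filter (200 genes, 500 UMIs, 20% mitochondrial) and a stricter filter (1000 genes, 2000 UMIs, 5%), doublets kept, resolutions 0.6 and 1.5, clustering without cell cycle, immediate early and interferon genes, centring per library, gates on cells thinned to 2000 UMIs, size factors from the median of ratios, a total without ribosomal protein and mitochondrially encoded genes, means of per-cell CPM, thinned cells, other minimums for list members, and class shares held equal. Alternatives chosen after seeing the data were the use of genes with at most 5 kb of introns for ratios and for clustering, subtraction of the median of genes of like intron length (10 bins) or transcript length (20 bins), clustering controls and GIA libraries apart, removal of the highest doublet scores, and a total without 3 rRNA-overlapping genes. Gene structures came from GENCODE mouse release 21, which matched 32235 genes. The gene procedure was tested on Poisson counts simulated from the young control profile with the totals of the old and young controls. Of changed genes, 52% at 1.5-fold, which is also the threshold for a call, and 100% at 3-fold were called. Of 4870 unchanged genes 0% were, and 95.1% of their intervals held the true ratio. The simulation holds no variation between mice, libraries or cells, so these values describe counting error only. Of 100 random lists, 7% lay outside the middle 95%. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. B cell-like and myeloid or dendritic cell-like cells were left out of gene levels, while unnamed cells were kept in.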

Results

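The series holds single-cell 3' RNA sequencing of CD4+ T cells sorted from inguinal lymph nodes of DBA/1 mice, an inbred strain used in arthritis research. Young mice (8 weeks) and old mice (14 to 15 months) were taken 14 days after immunisation with glucose-6-phosphate isomerase, which induces arthritis (GIA), or after an injection of saline (control). Each of the 4 groups is 1 library made from a pool of 4 mice, so the design crosses age with arthritis and has no replicate libraries. No test across mice is possible, no p-value is given, and each difference describes 1 library against another. The libraries held 8655 (young control), 7865 (young GIA), 9050 (old control) and 11045 (old GIA) cell barcodes, with 49298593, 47367069, 46361927 and 64014165 UMIs (unique molecular identifiers, each standing for 1 captured transcript). Median UMIs per barcode were 5127, 5505, 4566 and 4957. The cell filters kept 7812, 7573, 8714 and 10808 cells. Levels are given as CPM (counts per 1000000 UMIs of the same cells) over all CD4 T-like cells unless a class is named, and intervals are 95% intervals, simulated for ratios of ratios and exact otherwise, that cover counting error only, not differences between mice. Intervals of gene levels and ratios treat each UMI as independent. They do not cover the spread between cells, which matters most for genes with few UMIs.

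Clustering gave naive-like cells, which carried Lef1, Igfbp4 and Dapl1, and made up between 56.1% (old GIA) and 68.7% (old control) of the cells. Treg-like cells were marked by Foxp3, Il2ra and Ikzf2, and Tfh-like cells (T follicular helper, the cells that help B cells in germinal centres) by Cxcr5, Tox2, Il21, Sostdc1 and Tnfsf8. The Tfh-like class also took in other antigen-experienced helper cells, since its largest clusters carried Cxcr6 and Il1r1 as well. No cluster was named memory/effector-like or Th1-like. Small clusters were cycling-like, early-activation-like or interferon-response-like, the last with 0.0128%, 0.145%, 0.0115% and 2.20% of cells in young control, young GIA, old control and old GIA. Clustering centred per library drew these lines elsewhere: it named a Th1-like cluster (3.52%, 4.04%, 7.13% and 5.82%) and put interferon-response-like cells at 3.26%, 1.92%, 3.33% and 5.61%. B cell-like cells made up 1.77%, 1.23%, 0.471% and 0.842% of cells in young control, young GIA, old control and old GIA, and myeloid or dendritic cell-like cells 1.69%, 0.449%, 0.459% and 0.435%. These non-T cells were left out of the CD4 T-like cells (7541, 7444, 8632 and 10670). A cluster of 33 cells stayed unnamed and was counted among the CD4 T-like cells. GIA and control cells fell into different clusters: Tfh-like cells into clusters 5 and 11 in GIA and cluster 6 in controls, Treg-like cells into clusters 8 and 10 in GIA and cluster 7 in controls, and naive-like cells into clusters 0 and 1 in GIA and clusters 2, 3 and 4 in controls. Naive-like GIA cells also split by age. Cluster 0 held 5828 old GIA and 200 young GIA cells, and cluster 1 held 231 old GIA and 4922 young GIA cells.

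**Figure D1:**
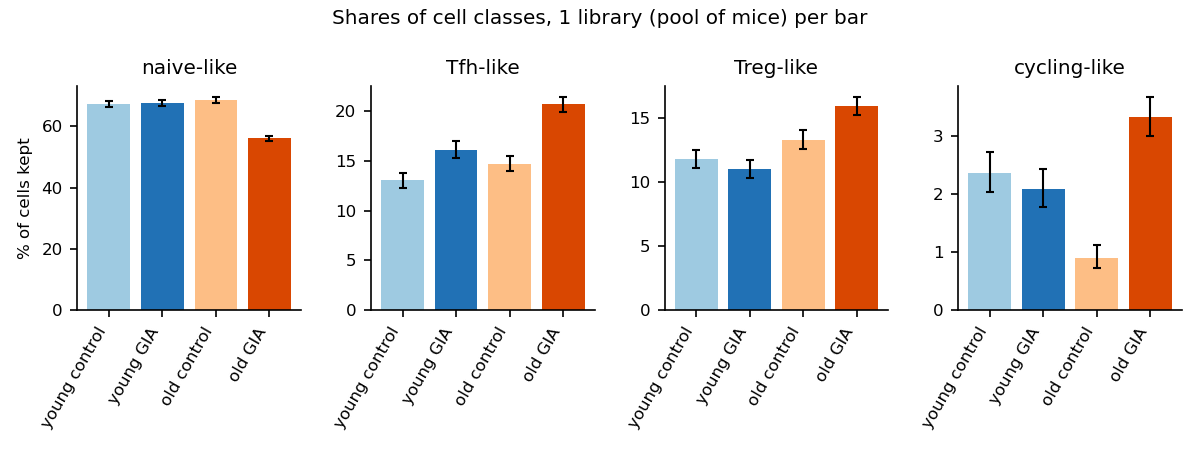
Share of cells kept (y axis, %) in 4 cell classes for each of the 4 libraries (1 bar per library, each a pool of mice; bars start at 0 and whiskers are exact binomial 95% intervals). The old GIA library has the lowest naive-like share (56.1%) and the highest Tfh-like (20.6%), Treg-like (15.9%) and cycling-like (3.32%) shares of the 4.

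The files show that the control libraries were written by Cell Ranger 7.0.1 and the GIA libraries by 6.0.1. In both ages genes with long introns were lower in GIA: genes were put in 10 bins of equal size by total intron length, and in the bin with the longest introns the median log2 ratio of GIA to control was -1.65 in young and -1.72 in old, against 0.09 and 0.21 in the bin with the shortest introns. Between old and young libraries counted by the same version the longest bin stood at 0.26 (controls) and 0.18 (GIA), and the shortest at 0.04 and 0.18. The median log2 ratio of all genes was -0.27 (GIA to control, young), -0.21 (old), 0.13 (old to young, controls) and 0.21 (GIA), and list medians are read against these. The comparisons of old with young are therefore given first, and in comparisons of GIA with control a value after subtraction of the median of genes of like intron length is called intron-corrected and given beside the measured one for lists, for the genes given in every comparison, and for list members that it moves by over 1.5-fold. The correction takes the same value from every gene of a bin, so for a single gene it is approximate and has no interval.

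**Figure D2:**
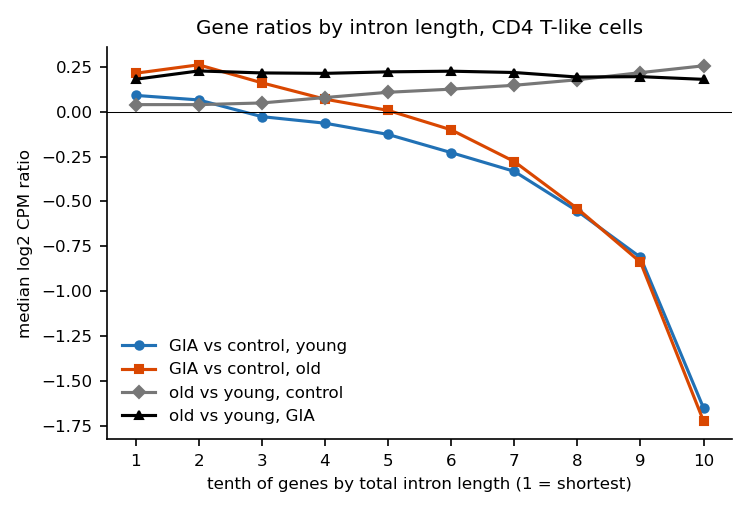
Median log2 CPM ratio (y axis) of genes in each of 10 bins of total intron length (x axis, 1 is the shortest) for the 4 comparisons over CD4 T-like cells. The lines for GIA against control end at -1.65 (young) and -1.72 (old) in the longest bin, while those for old against young end at 0.26 (controls) and 0.18 (GIA).

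The comparison of old with young mice under GIA asks how the CD4 T cell response to the same immunisation differs with age. Genes induced by interferons were higher in old GIA: 15 of 17 measured members of the interferon-response list were at least 1.5-fold higher, 0 were lower and 2 were neither. Ifit3, an antiviral protein induced by interferon, stood at 52.1 against 5.83 CPM (8.94-fold, interval 7.90 to 10.2). Ifit3b was 8.82-fold, Rsad2 (viperin) 5.54-fold and Oasl2 5.18-fold higher. The list's median log2 ratio was 1.45, above all 10000 random lists of matched expression. Other members were Usp18 (4.17-fold), which removes ISG15 from proteins, and Irf7 (3.75-fold), a transcription factor of the interferon response. Outside the list, the 12 genes named as highest included Ly6a (2.66-fold) and Apoe (3.84-fold), a lipid carrier. Within the same cells, marker lists of other cell types also differed: 4 of 7 B cell genes were higher and 0 lower (median 0.68), 5 of 10 myeloid or dendritic cell genes higher and 3 lower (median 0.48, with Lyz2 2.36-fold), and 2 of 3 erythroid or platelet genes lower and 0 higher (median -3.90). Of 4 gamma-delta T cell genes 2 were higher and 0 lower (median 0.58, percentile 89.0 of random lists).

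Treg and Tfh markers were also higher in old GIA. Of 13 Treg genes 7 were higher, 0 lower and 6 neither (median log2 0.65), among them Nrp1 (1.84-fold), Itgae (1.77-fold) and Ctla4, an inhibitory receptor (1.71-fold). Foxp3, the transcription factor that defines regulatory T cells (mm10 chromosome X, 7573644 to 7595245), stood at 48.3 against 29.2 CPM (1.65-fold, 1.55 to 1.76), and within the Treg-like class at 252 against 197 CPM. Treg-like cells made up 15.9% of old GIA and 11.003% of young GIA cells (ratio 1.45, 1.33 to 1.58). Of 14 Tfh genes 6 were higher, 0 lower and 8 neither (median 0.43), with Sostdc1 2.72-fold, Slamf6 1.67-fold and Pdcd1, which encodes the receptor PD-1 (chromosome 1, 94038305 to 94052553), 1.91-fold higher (50.5 against 26.5 CPM). Cxcr5, the receptor that takes T cells into follicles, was 1.55-fold higher, and Tnfsf8 (CD30 ligand) 1.31-fold. Tfh-like cells made up 20.6% against 16.1% (ratio 1.28, 1.20 to 1.38), while naive-like cells made up 56.1% against 67.7% (ratio 0.829, 0.798 to 0.860). Cycling-like cells made up 3.32% against 2.09% (ratio 1.59). The lists for senescence-associated T cells (4 of 8 higher, with Cebpa 2.16-fold and Lag3 1.78-fold), MHC class I antigen presentation (7 of 14 higher, with H2-T22 1.82-fold and Tap1 1.74-fold), glycolysis (5 of 14 higher, with Pkm 1.68-fold and Gapdh 1.67-fold) and NF-kB targets (4 of 11 higher, with Traf1 2.09-fold) had no lower member. These counts include the median log2 ratio of 0.21 that all genes had in this comparison. After subtraction of the median of genes of like intron length, which takes out that shift, 13 of 17 interferon-response, 2 of 13 Treg, 2 of 14 Tfh, 4 of 8 senescence-associated, 1 of 14 MHC class I, 0 of 14 glycolysis and 1 of 11 NF-kB genes were at least 1.5-fold higher and 0 lower. The list medians were then 1.27, 0.43, 0.23, 0.46, 0.33, 0.32 and 0.32. The senescence-associated list shares Pdcd1, Sostdc1 and Tnfsf8 with the Tfh list, and Pdcd1, Lag3 and Cd200 with the inhibitory receptor list. The counts of these lists therefore overlap.

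Effector cytokines went in different directions between old and young GIA. Il17a, the cytokine of Th17 cells, was at 0.461 against 3.81 CPM (0.121-fold, 0.0788 to 0.180) and Il17f at 0.532-fold, while Il22 was 1.72-fold and Ccr6 1.79-fold. Ifng, the main cytokine of Th1 cells, was 2.11-fold higher (1.47 to 3.09) at 1.86 against 0.882 CPM, Ccl5 2.25-fold and Cxcr3 2.24-fold; of 10 Th1 genes 4 were higher, 1 lower and 5 neither (3 higher and 1 lower after that subtraction). Cd44, an adhesion receptor of antigen-experienced cells, was 1.43-fold. In Tfh-like cells the 5 genes named as highest were Penk (12.5-fold), Ifi44, Ifit3, Dhx58 and Apoe. In Treg-like cells they included Ifit3 (6.38-fold), Oas1a, Irf7 and Usp18. In naive-like cells, mostly of cluster 0 in old and of cluster 1 in young GIA, they were Ifit1 (4.60-fold), Rtp4, Irf7, Usp18 and Fos. The lowest genes in all 3 classes included AY036118 (47.3 against 1110.1 CPM overall), Gm42418 and Lars2, which overlap ribosomal RNA sequences, and the 12 lowest overall held 7 histone genes. The Tfh-like ratio was 1.05 (0.956 to 1.15) with the stricter cell filter, 2.04 for cells with UMIs of both Cxcr5 and Pdcd1 after thinning, and 2.01 with clustering on genes with at most 5 kb of introns. The gate on Cxcr5 and Pdcd1 also follows the level of both genes per cell, and Pdcd1 was 1.49-fold higher within Tfh-like cells.

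In the controls, the comparison of old with young mice asks which differences come with age alone. Old controls had higher levels of Th1 genes and of some cytotoxic genes. Of 10 Th1 genes 4 were higher, 0 lower and 6 neither (median log2 0.50): Ccl5, a chemokine of memory and effector T cells (chromosome 11, 83525778 to 83530518), was at 124 against 25.9 CPM (4.78-fold, 4.49 to 5.09), Ifng 3.61-fold (2.37 to 5.67), and Nkg7 1.93-fold higher. Of 12 cytotoxic genes 5 were higher, 0 lower and 7 neither (median 0.29). Gzmk (granzyme K) stood at 3.998 against 0.0214 CPM, the latter from 1 UMI (ratio 187, interval 33.2 to 7428), Ccl4 was 5.74-fold, and Eomes, a transcription factor of cytotoxic and memory T cells, 2.16-fold higher. The percentiles of the Th1 and cytotoxic lists among random lists were 99.97 and 94.39, so the cytotoxic list lay inside the middle 95%. Within Tfh-like cells Gzmk was at 20.2 against 0 CPM, at least 47.8-fold higher against a floor of 3 counts, and Ccl5 at 754 against 89.9 CPM. The Tfh-like class also holds other helper cells. Centred clustering named 7.13% of old and 3.52% of young control cells Th1-like. Whether Gzmk and Ccl5 came from such cells was not tested. Il7r, the receptor subunit for IL-7, was 2.52-fold higher over all CD4 T-like cells and 2.31-fold within naive-like cells. Itga4, an integrin for entry into inflamed tissue, was 2.10-fold, Cxcr4 2.62-fold and Cxcr3 1.96-fold higher, and 5 of 17 homing receptors were higher with 0 lower. Nrp1 was 2.12-fold and Ly6a 2.04-fold higher. Interferon-response genes had 4 of 17 higher and 0 lower (median 0.43), with Oasl2 1.84-fold and Rtp4 1.78-fold.

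Th17, cell cycle and respiratory chain genes were lower in old controls. Of 11 Th17 genes 5 were lower, 0 higher and 6 neither (median -0.33): Il17a was at 0.132 against 2.05 CPM (0.0642-fold, 0.0230 to 0.145), Il17f at 0.157-fold, Il22 at 0.202-fold and Il1r1 at 0.499-fold. Marker lists of other cell types were also lower within the same cells: lymphoid tissue inducer cells (median -0.68, 3 of 5 lower; Il1r1 is on this list and the Th17 list), NK cells (-1.30, 2 of 4 lower), B cells (-0.98, 4 of 7 lower), myeloid or dendritic cells (-0.70, 5 of 10 lower and 2 higher) and erythroid cells or platelets (-1.80, 3 of 3 lower). The gamma-delta T cell list went the other way (median 0.58, 2 of 4 higher and 0 lower, percentile 95.7 of random lists). Il2, the T cell growth factor, was at 0.155-fold. Of 15 cycling genes 8 were lower, 0 higher and 7 neither (median -0.68), with Pclaf at 0.487-fold and Cdk1 at 0.553-fold, and cycling-like cells made up 0.907% against 2.36% (ratio 0.385). With the cell class shares held equal the cycling median was 0.22, against 0.15 for all genes. Of 19 nuclear-encoded respiratory chain genes 4 were lower, 0 higher and 15 neither (median -0.33, below all random lists), with Ndufa1 at 0.489-fold and Cox7c at 0.552-fold. The 12 genes named as lowest held 7 histone genes, Snrpf, Cd200, Ndufb1-ps, Tomm7 and Cox17. Foxp3 (0.977-fold), Cxcr5 (0.927-fold), Pdcd1 (1.22-fold), Cd44 (1.09-fold) and Tnfsf8 (1.11-fold) stayed within 1.5-fold. In Treg-like cells the genes named as highest were Nr3c2 (46.5 against 4.40 CPM, 10.6-fold), the mineralocorticoid receptor, Oas1a (7.77-fold), Prss12, B3galt1 and Bmpr1a, and Dapl1, a marker of naive cells, was lowest at 0.287-fold. Naive-like shares were 68.7% and 67.4% (ratio 1.02, 0.983 to 1.06). Treg-like shares were 13.3% and 11.8% (ratio 1.13, 1.03 to 1.23), and Tfh-like shares 14.7% and 13.0% (ratio 1.13, 1.04 to 1.23). Both of these last ratios turned under alternatives: cells with a Foxp3 UMI after thinning gave 0.929 in place of the Treg-like ratio, and 3 other clusterings put the Tfh-like ratio between 0.627 and 0.869, or between 1.06 and 1.104 with Th1-like and memory/effector-like cells counted in.

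**Figure D3:**
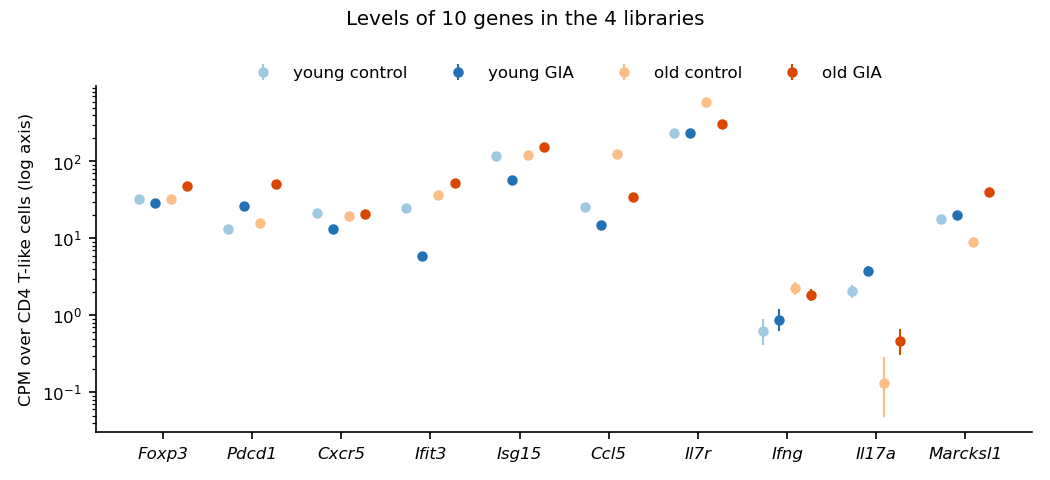
Level of 10 genes (y axis, CPM over CD4 T-like cells, log axis) in the 4 libraries (colours), with exact Poisson 95% intervals as lines. Pdcd1 is highest in old GIA (50.5 CPM), Ccl5 in old control (124 CPM) and Il17a in young GIA (3.81 CPM), and Ifit3 is lowest in young GIA (5.83 CPM).

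The comparison of GIA with control in old mice asks which genes differ with arthritis in old CD4 T cells. Cell cycle genes, Tfh genes and T helper cytokines were higher in old GIA. Of 15 cycling genes 14 were higher, 0 lower and 1 neither (median log2 1.03, intron-corrected 0.96), with Cdk1 2.90-fold and Rrm2, a subunit of the enzyme that makes DNA precursors, 2.88-fold, and cycling-like cells made up 3.32% against 0.907% (ratio 3.66, 2.86 to 4.74). With class shares held equal the cycling median was -0.11 and the Tfh median 0.065, where the median of all genes was -0.30. Both lists thus lay nearer to all genes but still above them. The stricter cell filter gave a Tfh median of 0.29. Pdcd1 stood at 50.5 against 16.0 CPM (3.15-fold, 2.91 to 3.42; intron-corrected 3.13) and Sostdc1, a secreted inhibitor of BMP and Wnt signals, 2.65-fold. Of 14 Tfh genes 7 were higher, 2 lower and 5 neither (median 0.50, intron-corrected 0.63). The 2 lower genes were Bcl6, the transcription factor of follicular helper cells, at 0.252-fold (intron-corrected 0.270), and Tox at 0.295-fold (intron-corrected 0.974). The senescence-associated list, which also holds Pdcd1 and Sostdc1, had 5 of 8 higher and 0 lower (median 1.37, intron-corrected 1.17), with Cebpa 5.78-fold and Cd200 2.60-fold. Of 15 T helper cytokines and TNF family ligands 7 were higher and 2 lower (median 0.57, intron-corrected 0.49). Il2 was 8.73-fold (5.53 to 14.5), Il22 8.24-fold (5.51 to 12.8) and Il17f 2.95-fold higher, while Cd40lg, the ligand by which T cells activate B cells, was at 0.324-fold. Il17a was 3.50-fold (1.43 to 10.3), at 0.461 against 0.132 CPM (intron-corrected 2.74), and Ifng 0.831-fold (0.631 to 1.09; intron-corrected 0.742).

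Other groups followed in old mice. Of 12 memory/effector genes 5 were higher and 0 lower (median 0.47, intron-corrected 0.44), with Anxa2 1.71-fold (intron-corrected 2.07) and Vim 1.69-fold. With class shares held equal the list median was -0.044 and Anxa2 0.926-fold, both without intron correction. The median of all genes was then -0.30, so the list still lay above it. Of 13 Treg genes 4 were higher and 2 lower before and 8 higher and 1 lower after intron correction, with Tnfrsf4 (OX40) 1.87-fold and Capg 1.76-fold, and Foxp3 was 1.497-fold higher (1.41 to 1.59; intron-corrected 1.60). Of 14 glycolysis genes 6 were higher and 2 lower (8 and 1 after intron correction), with Tpi1 2.17-fold and Pkm 1.90-fold. Th1 genes had 5 of 10 lower, with Ccl5 at 0.275-fold and Il12rb2 at 0.107-fold (intron-corrected 0.197). Of these genes 1 was higher, Cxcr3 at 1.66-fold (intron-corrected 1.38), so that after intron correction 5 were lower and 0 higher. The Th1 list median was -0.59 (intron-corrected -0.58), at percentile 15.8 (intron-corrected 2.73) of random lists. Both lay above percentile 2.5, the corrected one only just. Interferon-response genes had 1 of 17 higher, Isg20 at 1.58-fold, and 0 lower (median 0.39, intron-corrected 0.26, the latter at percentile 80.9 of random lists). The measured median was 0.10 without the interferon-response-like cluster, which has 238 old GIA cells and 1 old control cell, and 0.22 without the cells so named by centred clustering. Among marker lists of other cell types, 4 of 7 B cell genes (median 0.64, intron-corrected 0.41) and 3 of 5 plasma cell genes (median 1.17, intron-corrected 0.96) were higher and 0 lower, with Jchain at 2.64 against 0.198 CPM. The genes named as highest also held Marcksl1, an actin regulator (4.38-fold), Snrpf (3.77-fold), Rpa3 (3.85-fold), Il1r2, a decoy receptor for interleukin-1 (3.12-fold), Penk, the precursor of enkephalins (2.79-fold), and Cenpf (2.69-fold). In Tfh-like cells they were Gfra4 (7.003-fold), Ascl2, a transcription factor of follicular helper cells (7.82-fold), Il1r2 (5.75-fold), Il22 and Cebpa; Gfra4 and Ascl2 are leading genes of cluster 11, which is made up almost wholly of GIA cells. Naive-like cells made up 56.1% against 68.7% (ratio 0.816, 0.787 to 0.846), Treg-like cells 15.9% against 13.3% (1.20, 1.11 to 1.29) and Tfh-like cells 20.6% against 14.7% (1.41, 1.31 to 1.51). Cxcr5 was at 1.06-fold (intron-corrected 1.54), Cd44 at 0.762-fold (intron-corrected 1.36) and Tnfsf8 at 1.16-fold (intron-corrected 1.403). Within Tfh-like, Treg-like and naive-like cells, measured Cxcr5 was at 1.09-fold, 0.672-fold and 0.117-fold. Cd44 was at 0.598-fold, 0.720-fold and 0.269-fold there. These within-class values carry no intron correction. In log2, Cd44 was at -0.74, -0.47 and -1.90, where genes of like intron length had medians of -0.81, -0.78 and -0.88. Cxcr5 was at 0.13, -0.57 and -3.09, where such genes had -0.53, -0.54 and -0.64. In naive-like cells both genes lay below such genes, but version and condition cannot be told apart there. The 12 genes named as lowest, such as Flg and Fgfr2 (0 UMIs in old GIA, at least 1276-fold and 1007-fold lower against a floor of 3 counts), were at most 1.66 CPM in young GIA as well. The stricter cell filter lowered the Tfh-like ratio to 1.09 (1.00 to 1.20), while cells with UMIs of both Cxcr5 and Pdcd1 after thinning gave 3.46. That gate also follows the level of both genes per cell, and Pdcd1 was 2.55-fold higher within Tfh-like cells.

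In young mice, the same comparison of GIA with control asks which genes differ at 8 weeks of age. Some senescence-associated genes, Pdcd1 among them, were higher, and interferon-response genes lower. Pdcd1 stood at 26.5 against 13.1 CPM (2.02-fold, 1.83 to 2.23; intron-corrected 2.20). Of 8 senescence-associated genes 4 were higher, 1 lower and 3 neither (median log2 0.59, intron-corrected 0.62), with Cebpa 2.96-fold, Sostdc1 2.54-fold and Lag3, an inhibitory receptor, 1.76-fold. Il4, the Th2 and Tfh cytokine, was 2.30-fold higher, and 3 of 14 Tfh genes were higher, 3 lower (Tox at 0.263-fold, intron-corrected 0.827, and Bcl6 at 0.297-fold among them) and 8 neither, while after intron correction 5 were higher and 1 lower. Of 12 cytotoxic genes 4 were higher, 0 lower and 8 neither, with Ccl4 3.38-fold, Klrg1 1.97-fold and Gzmb 1.62-fold. The list median was -0.00 at percentile 96.2 of random lists, and intron-corrected 0.37 at percentile 99.8. Il17a was at 3.81 against 2.05 CPM (1.86-fold, 1.44 to 2.41; intron-corrected 1.77) and Ifng 1.42-fold (0.863 to 2.38; intron-corrected 1.44). Interferon-response genes were lower in young GIA: 10 of 17 were lower, 0 higher and 7 neither (median -0.89, intron-corrected -0.63), with Ifit3 at 0.233-fold and Rsad2 at 0.222-fold. Within the same cells 7 of 10 myeloid or dendritic cell genes were also lower and 0 higher (median -1.13, intron-corrected -1.15). So were 4 of 7 B cell genes, with 0 higher (median -0.87, intron-corrected -0.79). Among random lists the first median was at percentile 4.86 (intron-corrected 0.66) and the B cell median at 16.8 (intron-corrected 7.86). Only the intron-corrected myeloid or dendritic cell median lay below percentile 2.5. Th1 genes had 4 of 10 lower (3 after intron correction), with Il12rb2 at 0.179-fold (intron-corrected 0.318) and Ccl5 at 0.584-fold. The Th1 list median was -0.40 (intron-corrected -0.28), at percentile 34.0 (intron-corrected 8.68) of random lists. Random lists of matched expression thus often lay as low. Of 12 memory/effector genes 1 was higher, S100a11 at 1.60-fold, and 1 lower, Cd44 at 0.583-fold (intron-corrected 1.02), while after intron correction 3 were higher and 0 lower.

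Of the class shares in young mice, Tfh-like cells made up 16.1% against 13.0% (ratio 1.24, 1.14 to 1.34), Treg-like cells 11.003% against 11.8% (0.934, 0.850 to 1.03) and naive-like cells 67.7% against 67.4% (1.00, 0.966 to 1.04). The Tfh-like ratio was 1.13 with the stricter cell filter. Cells with UMIs of both Cxcr5 and Pdcd1 after thinning, a gate that also follows the level of these genes per cell, gave 2.51. Foxp3 was at 0.885-fold (intron-corrected 1.04), Cxcr5 at 0.634-fold (intron-corrected 0.931) and Tnfsf8 at 0.982-fold (intron-corrected 1.24). In Tfh-like cells Gfra4 (4.89-fold), Krt83 (3.21-fold), Ifitm1 (3.11-fold) and Pdcd1 (117 against 49.6 CPM, 2.36-fold) were among the 5 named as highest, and among genes with at most 5 kb of introns Gal, the neuropeptide galanin (13.8-fold), and Ascl2 (4.75-fold). Over all CD4 T-like cells the genes named as highest were Rpa3 (2.78-fold), Ost4 (2.16-fold), Atxn2l, Sdhd, Srsf9, Ddit4, Pdcd1, H2-T23 (1.88-fold), Snrpf, AY036118, Snhg6 and Smim26; Rpa3, Ost4, Pdcd1 and Snrpf were also named in old mice. The 12 named as lowest again held Flg and Fgfr2 with 0 UMIs in GIA. Hemoglobin transcripts, which mark red blood cells, were higher in young GIA (Hbb-bs 10.5 against 1.18 CPM, 8.97-fold).

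**Figure D4:**
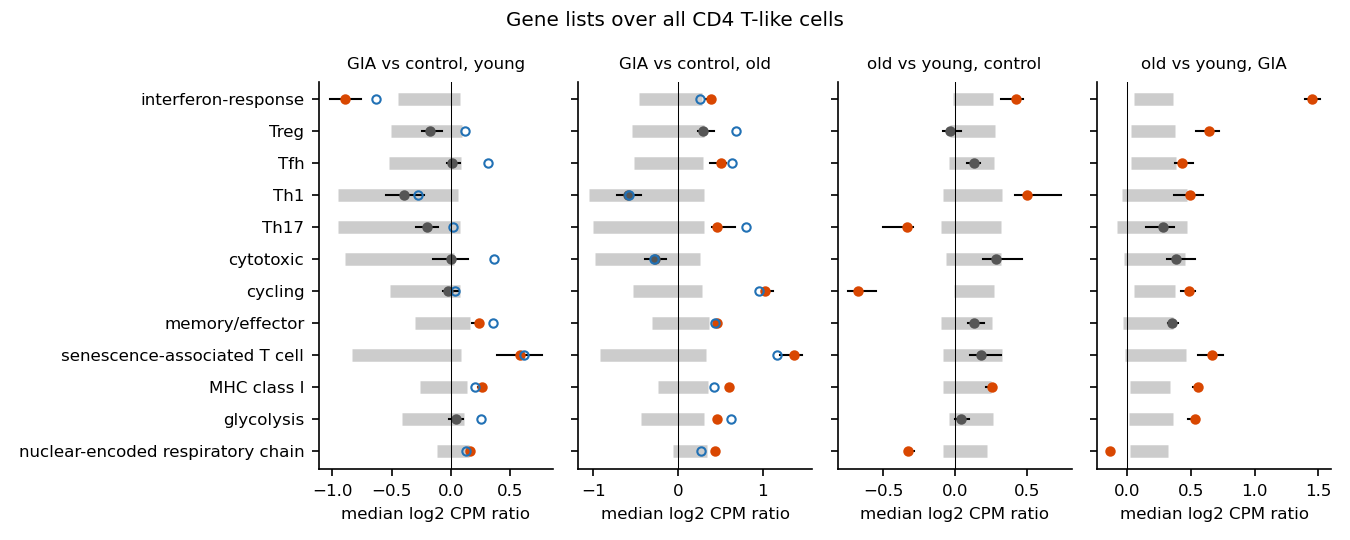
Median log2 CPM ratio (x axis) of 12 gene lists (y axis) in the 4 comparisons over CD4 T-like cells. Filled points are medians (orange where outside the middle 95% of 10000 random lists of matched expression, which the grey bars show), black lines their counting intervals and open circles the intron-corrected medians. The interferon-response list lies at -0.89 for GIA against control in young, 0.39 in old, and 1.45 for old against young GIA.

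Dividing the ratio of GIA to control in old mice by that in young mice cancels effects of the software version that act alike on a gene at both ages. The ratio of ratios is taken after adding 0.5 UMIs to each count, and genes were ranked by the interval bound nearest to 1. The 8 named as highest were Ifit3 (6.15, 5.31 to 7.12), Marcksl1 (3.91), Ifit1 (3.58), Gm9844, Hist1h2ap, Isg15 (2.72), which encodes a ubiquitin-like protein induced by interferon, and the cell cycle genes Pclaf (2.75) and Cdca8 (2.86). With class shares held equal it was 0.835 for Pclaf, 0.935 for Cdca8 and 0.858 for Hist1h2ap. The ratio of ratios was 1.69 for Foxp3 (1.54 to 1.87), 1.67 for Cxcr5 (1.48 to 1.88), 1.56 for Pdcd1 (1.37 to 1.77), 1.31 for Cd44 and 1.18 for Tnfsf8. The intervals included 1 for Il17a (1.77, 0.840 to 6.02) and Ifng (0.586, 0.339 to 1.01). The first named as lowest were AY036118 (0.0436), Gm42418 (0.131), Lars2 (0.144), Gm15564 (0.133) and Il31ra (0.142). Gm15564 was at 317.5 and 193.2 CPM in young and old controls but at 1.66 and 0.127 CPM in young and old GIA. Il31ra was at 120.7 and 159.0 CPM in controls but at 0.882 and 0.159 CPM in GIA. Both ratios thus rest on low levels in GIA, and no age difference is read from them. For shares of cells it was 1.28 for Treg-like (1.15 to 1.44), 0.813 for naive-like (0.788 to 0.838), 4.14 for cycling-like (3.05 to 5.79) and 1.14 for Tfh-like cells (1.03 to 1.26), the last turning to 0.967 with the stricter cell filter.

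Single-gene gates set the class shares against another measure. After each cell was thinned to 2000 UMIs, cells with a Foxp3 UMI made up 4.90%, 4.48%, 4.55% and 7.04% of CD4 T-like cells in young control, young GIA, old control and old GIA (9.24%, 8.17%, 8.18% and 12.7% unthinned). Cells with UMIs of both Cxcr5 and Pdcd1 made up 0.336%, 0.844%, 0.498% and 1.72% (1.79%, 2.39%, 1.44% and 4.20% unthinned). This share depends on the level of both genes in a cell as well as on cell numbers. Within Tfh-like cells Pdcd1 was 2.36-fold (young) and 2.55-fold (old) higher in GIA than in control. Cxcr5 has 46.8 kb of introns, so the software version may also enter between GIA and control. Cells with S100a4, a marker of memory and effector cells, made up 7.38%, 7.42%, 10.7% and 12.9%, against 4.59%, 2.90%, 7.89% and 3.28% of B cell-like cells. Thinning left out 90, 96, 192 and 171 shallower cells. In B cell-like cells, which should lack Foxp3, 2.75% had a Foxp3 UMI in young control after thinning and 0% in the other 3 libraries, where a count of 0 allows up to 5.21%, 9.25% and 5.87%, and for Cxcr5 with Pdcd1 the shares were 0%, 1.45%, 0% and 0%. Median UMIs were 5385, 5623.5, 4653 and 5001 in CD4 T-like and 3508, 3241, 5100 and 3335 in B cell-like cells.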

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

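The tests of intron counting, of naive-like cells alone, of the cells drawn by centred clustering and of scaling for interferon genes were chosen only after the result was seen. With 1 library per group, none of the differences between ages or between conditions given here was tested.

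The first pattern is that ratios of GIA to control follow gene structure. The median log2 ratio of genes with the longest minus those with the shortest introns (outer of 10 bins) was -1.74 in young and -1.94 in old, which is consistent with introns counted in the control libraries and not in the GIA libraries. A response to GIA in antigen-experienced cells argues for a stronger trend in Tfh-like than in naive-like cells, but the trends differed by 0.10 and 0.029. Exons inside another gene on the same strand were no account of the genes named higher, since 0 of 12 in young and 0 of 12 in old had at least 50% overlap. Only 2.5% of measured genes have such overlap. Among genes with at most 5 kb of introns, the median log2 ratio was 0.32 with such overlap and 0.05 with less in young, and 0.52 and 0.21 in old. For old against young it was 0.20 and 0.04 in controls and 0.31 and 0.21 in GIA, so overlapped genes stood higher in each comparison. The effect of GIA itself on genes with long introns stays open, since version and condition coincide.

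The second pattern is the higher level of interferon-response genes in old than in young GIA (median log2 1.45). Without the interferon-response-like cluster it was 1.30, and 1.28 without the larger group of such cells that clustering centred per library drew. It was 1.34 in naive-like cells, which were mostly of cluster 0 in old GIA and of cluster 1 in young GIA. With size factors from the median of ratios it was 1.26. These values argue against a larger share of interferon-response-like cells, against more Treg-like and Tfh-like cells, and against scaling as the whole of the pattern. Age, or a difference between these particular pools of mice in housing, infection or handling, may underlie it, and neither was tested. Ifit3 stood at 25.03 CPM in young control, 5.83 in young GIA, 36.4 in old control and 52.1 in old GIA, so the contrast also rests on low levels in young GIA.

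The third pattern is the lower level of nuclear-encoded respiratory chain genes in old than in young controls (median log2 -0.33). It was -0.37 after the trend with transcript length was subtracted and -0.26 with class shares held equal. The median of all genes was 0.13 as measured, 0 after that subtraction and 0.15 with class shares held equal. Against all genes the list thus lay somewhat nearer in both settings, but still below. These values argue against lower recovery of short transcripts and against the make-up of cell classes as the whole of the pattern. Between the other pair of pools, old against young GIA, the median was -0.13 at percentile 0.03 of random lists, with 1 gene higher and 0 lower. After subtraction of the median of genes of like intron length it was -0.35, with 0 higher and 2 lower, against -0.38 in controls. Age and a difference between the pools stay open and untested.

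The next values stand here because, as measured, they went in opposite directions in the 2 ages or the 2 conditions. The ratio of GIA to control in young and in old was 0.233 and 1.43 for Ifit3, 0.382 and 1.37 for Ifit1, and 0.477 and 1.30 for Isg15. It was 0.647 and 1.73 for Hist1h2ap, 0.924 and 2.54 for Pclaf, and 0.765 and 2.19 for Cdca8. It was 1.81 and 0.0790 for AY036118, and 0.885 and 1.497 for Foxp3, where the intron-corrected 1.04 and 1.60 were not opposite. The interferon-response list median was -0.89 in young and 0.39 in old, intron-corrected -0.63 and 0.26, the last at percentile 80.9 of random lists. In old it was 0.021 in naive-like, 0.16 in Treg-like and -0.39 in Tfh-like cells, and 0.10 without the interferon-response-like cluster, all of which leave out 238 old GIA cells and 1 old control cell. Without the 606 old GIA and 290 old control cells so named by centred clustering it was 0.22, so the size and direction in old depend on which cells are counted. Between old and young the cycling list median was -0.68 in controls and 0.48 in GIA, the B cell list median -0.98 and 0.68, and the ratio of cycling-like shares 0.385 and 1.59. B cell-like cells stand here for another reason, as cells that the comparisons leave out, and made up 0.842% of old GIA and 0.471% of old control cells.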

How the results depend on the processing

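The alternatives by intron length, by transcript length and by clustering controls or GIA apart were chosen only after the results were seen. Over all alternatives, 202 of 240 values for shares stayed within the counting interval of the reported value. So did 1492 of 2160 for lists and 2510 of 3542 for genes. The values counted as turned in direction were 6, 8 and 12 for shares, lists and genes. That count leaves out some changes of direction. With the intron trend subtracted, Cd44 went from 0.762 to 1.36 (GIA to control, old) and Foxp3 from 0.885 to 1.04 (young). The inhibitory receptor list median went from -0.47 to 0.23 (GIA to control, old). Shares under the looser filter, resolution 0.6, removal of the highest doublet scores and clustering without cell cycle, immediate early and interferon genes stayed within it in 25 of 25 cases each. Keeping called doublets tests nothing, since hardly any were called, but its values are included in the totals above. Clustering on genes with at most 5 kb of introns gave no Treg-like class, and the main clustering gave no memory/effector-like class for the planned share, so these have no value. Size factors and the total without ribosomal protein and mitochondrial genes move all genes of a comparison alike. They account for 112 and 85 of the list values outside the interval, a change of common scale. The cause of the other shifts below was not tested unless stated.

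Resolution 1.5 gave naive-like ratios of GIA to control of 1.05 (young) and 0.851 (old). The stricter filter gave naive-like 0.888 (GIA to control, old), 0.895 (old to young, GIA) and 0.867 (age difference), Tfh-like 1.13 and 1.09 (GIA to control, young and old), 1.05 (old to young, GIA) and 0.967 (age difference), and a Tfh list median of 0.29 (GIA to control, old). Variable genes with at most 5 kb of introns gave naive-like 0.857 (GIA to control, old), 0.904 (old to young, GIA) and 0.857 (age difference), and Tfh-like 2.80, 0.869 (old to young, controls), 2.01 and 2.31. Gates after thinning also follow the level of the gated genes per cell. In place of the Treg-like ratios, Foxp3 gave 1.55 (GIA to control, old), 0.929 (old to young, controls) and 1.69 (age difference). In place of the Tfh-like ratios, Cxcr5 with Pdcd1 gave 2.51 and 3.46 (GIA to control, young and old), 1.48 and 2.04 (old to young, controls and GIA) and 1.38 (age difference). Centring gave Tfh-like 1.95 (GIA to control, old), 0.719 and 1.09 (old to young, controls and GIA) and 1.52 (age difference). Clustering apart gave Tfh-like 0.627 (controls) and 1.46 (GIA).

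For list medians, size factors gave -0.61 (interferon-response, GIA to control, young), 0.71 (Tfh, GIA to control, old), 0.39 (Th1, old to young, controls) and 1.26 (interferon-response, old to young, GIA). The total without ribosomal protein and mitochondrial genes gave -0.75, 0.62 and 1.33 for the first, second and last of these, subtraction of the intron trend -0.63, 0.63, 0.38 and 1.27, and subtraction of the transcript length trend 0.68 (Tfh), 0.30 (Th1), 1.22 (interferon-response, old to young, GIA) and 0.016 (naive list, GIA to control, old). Size factors moved the median of all genes by 0.29 and 0.20 (GIA to control, young and old) and -0.11 and -0.19 (old to young, controls and GIA). The total without ribosomal protein and mitochondrial genes moved it by 0.15, 0.11 and -0.12 for the lists given. These shifts of lists are thus those of all genes. Per-cell CPM gave 1.54 for interferon-response, old to young, GIA. With class shares held equal that list was at 1.28 and, for GIA to control in old, memory/effector at -0.044, Tfh 0.065, Th17 -0.033, cycling -0.11 and p53 targets with cell cycle inhibitors -0.13 (-0.023 among genes with at most 5 kb of introns). Cycling was at 0.22 (controls) and -0.099 (GIA) for old to young. The median of all genes with class shares held equal was -0.30 for GIA to control in old. For old to young it was 0.15 (controls) and 0.14 (GIA). The lists for GIA to control in old that turned below 0 with class shares held thus still lay above all genes.

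Holding class shares equal fixes the share of cycling cells by construction, and with it cell cycle genes turned: Rrm2 0.929, Cenpf 0.864, Cdk1 0.9751, Ccna2 0.823 and Pclaf 0.830, and also Anxa2 0.926 (GIA to control, old), Ccna2 1.195 and Cdk1 1.15 (old to young, controls), and Hist1h2ap 0.858, Pclaf 0.835 and Cdca8 0.935 (age difference). Turned here means across a ratio of 1, without intron correction. The median log2 ratio of all genes in this setting was -0.30 for GIA to control in old. Among the genes counted as turned, subtraction of the intron trend gave Cd44 1.02 (GIA to control, young).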

Other observations

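MHC class I genes, which present peptides to CD8 T cells, had 7 of 14 higher and 1 lower for GIA against control in old mice (median log2 0.60), with Tap2 at 2.07-fold and Nlrc5 at 0.229-fold, and 2 higher and 1 lower in young (median 0.26). After subtraction of the median of genes of like intron length, 3 were higher and 1 lower in old (median 0.43, Tap2 1.97-fold and Nlrc5 0.410-fold), and 2 higher and 1 lower in young (median 0.20). Immediate early and dissociation stress genes had 5 of 13 higher and 0 lower for old against young GIA (median 0.47), and 3 of 13 higher and 0 lower in controls (median 0.34). The median share of mitochondrial UMIs in cells kept was 3.21%, 3.19%, 3.56% and 4.08% in young control, young GIA, old control and old GIA, and Hbb-bs was at 0.0588-fold in old against young GIA. Inhibitory receptors had 3 of 10 higher and 0 lower for old against young GIA (median 0.40).

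Within Tfh-like cells (clusters 5 and 11 in GIA, cluster 6 in controls, with other helper cells among them), Il17a was at 1.07 CPM in old GIA against 17.2 CPM in young GIA (0.0621-fold, 0.0331 to 0.108), and at 0.777 CPM in old control against 7.75 CPM in young control (0.100-fold, 0.0313 to 0.248). Ifng in the same cells was at 5.79 against 3.58 CPM in GIA (1.62-fold, 1.04 to 2.57) and at 11.8 against 3.10 CPM in controls (3.81-fold, 2.34 to 6.43). Tyrobp, an adaptor of activating receptors, was at 0.198-fold in GIA and 0.264-fold in controls.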
